A study of Ovis aries with 10 samples.

How the data were processed

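Endometrial RNA of 10 ovariectomized ewes was measured by polyA RNA-seq. Per the labels' protocols, the endometrium was dissected from the uterus and snap frozen, RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit. All ewes received progesterone (P4) at 50 mg per day over 14 days. In 5 of them, RU486 (mifepristone, an antagonist of the progesterone receptor) was added at 50 mg per day from day 8 to day 14. Groups were taken from the treatment label of each sample. Replicate numbers follow the order of the samples and only name the ewes, so no pairing was used.

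The deposited table holds 1 row for each of 23020 sheep genes, given as Ensembl identifiers, with an adjusted p-value of the authors' own comparison of the groups and 1 expression value per ewe. The submitters' processing notes name cutadapt 1.11, HISAT2 2.0.3, featureCounts 1.5.0, edgeR and the genome build Oar_v3.1, with no role or order. The annotation, any filter on genes and the scaling of the libraries are not given in the sources used here. The file header does not name the unit of the expression values, which the authors rounded to 2 decimals. They are treated here as FPKM deposited by the authors (scaled by gene length and library size; whether reads or fragments were counted is not given in the sources used here), for reasons found in the values. The column sums differ between ewes, from 680815 to 965174, and do not reach the fixed total of CPM or TPM over all genes. Among 1353 genes with a value above 0 in a single ewe, the 10th percentile of that value was 0.022 and the 90th was 0.618. Such a spread would arise if the worth of 1 read differs between genes, unlike in CPM. Some of these genes may hold more than 1 read, so the spread alone does not settle it. These checks do not exclude TPM from which genes were removed, so FPKM is a reading of the unit and not a stated fact. The p-values were deposited by the authors as edgeR adjusted p, per the file header, and are reported as theirs.

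No sequencing depth is given, and counts could not be recovered from values rounded this coarsely. The relative depth of the libraries was estimated from rarely seen genes, those above 0 in at most 4 ewes. For each pair of libraries, the most frequent ratio of the values of at least 0.2 FPKM was taken as the ratio of what 1 read is worth. Under the reading as FPKM this gives relative depth if the libraries were scaled by their size alone. Any further scaling factor, which is not given, would enter the estimate. On a scale with a geometric mean of 1, the estimates ran from 0.773 to 1.16. Because the depth itself is unknown, no counting interval is given for any value, and the precision stated is the spread between ewes.

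The values were analysed as log2(FPKM + 1), a pseudocount of 1, with limma 3.58.1 in R 4.3.3 (linear model with 1 term for the group, empirical Bayes variances with a trend on mean expression). Calls were made at a Benjamini-Hochberg adjusted p under 0.05, called FDR below. The 1 gene at 0 in every ewe was left out, and 23019 genes were tested. Fold changes are P4+RU486 minus P4 on the log2(FPKM + 1) scale, which understates the change of genes near 0. The main analysis had been planned for counts, with limma on log2 values as the stated choice for a table without them. Single values were compared with exact permutation tests, two-sided, in which 5 ewes against 5 cannot go below 0.00794. The principal component analysis and the count of genes without overlap used the 14866 genes with a mean log2(FPKM + 1) of at least 1. The limma step was tested on simulated data made from the means and spreads of the genes tested for the comparison of P4+RU486 with P4. With 200 genes changed among 22996 fitted, 67% of the 100 genes changed by 1 on the log2 scale and 95% of the 100 changed by 2 were recovered, with 6 false calls. With no gene changed, the simulation gave 0 calls. The changed genes were drawn from those with a mean log2(FPKM + 1) of at least 1. Values were simulated independently, without shifts shared within a library, so these rates can differ in the real data.

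The table does not pair the identifiers with gene names. None of the 23020 identifiers matched the reference gene table at hand, so no gene names, coordinates or functions are given. For the same reason 25 gene lists fixed before the data were examined (steroid receptors, vesicle release, prostaglandin synthesis, cell type markers and others) could not be tested, and nor could the set tests and the scaling on ribosomal protein genes planned with them. The rule for named genes had asked for the 10 highest and 10 lowest fold changes among called genes with a symbol, a mean log2 of at least 1 and no overlap between the groups, for members of the lists and for the smallest p. Without symbols it was applied to identifiers, and the 2 highest and 2 lowest are named. Alternatives chosen before the data were examined were the filter on mean expression, the pseudocount, the FDR threshold, a minimum fold change, Bonferroni adjustment, centring on the median gene and leaving out each ewe. Array weights, rescaling by median ratios, quantile normalisation, the authors' adjusted p and a filter combined with leaving out 1 ewe were added after seeing the data. The alternatives planned for counts, among them other size factors and another count model, could not be run on these values.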

Results

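The series asks how progesterone regulates the sheep uterus, and this part of it profiled the endometrium, the inner lining of the uterus, in ewes without ovaries. The comparison is between ewes under continued progesterone (P4, n = 5) and ewes also given RU486 over its second part (P4+RU486, n = 5). It shows which transcripts differed under RU486 while the hormone was still given. How far RU486 blocked the progesterone receptor was not measured. Ewes are separate animals, so the spread between them includes animal-to-animal variation. The summed expression per ewe was 746636 ± 48022 FPKM in P4 and 778456 ± 106684 FPKM in P4+RU486 (mean ± SD, n = 5 each), and the highest was P4+RU486 replicate 2 with 965174 FPKM. The sums did not differ detectably between the groups (exact permutation test, two-sided, p = 0.714). Relative depth was 1.03 ± 0.147 in P4 and 0.99 ± 0.13 in P4+RU486 (SD, n = 5 each), and P4 replicate 3 was the shallowest library at 0.773. No 2 ewes had identical values.

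The treatment groups lay apart along the main axis of variation in the endometrial transcriptome. The first principal component held 31.8% of the variance of 14866 expressed genes, and every P4 ewe scored above every P4+RU486 ewe. Scores were 22.0 ± 11.4 in P4 and -22.0 ± 18.8 in P4+RU486 (SD, n = 5 each; exact permutation test, two-sided, p = 0.00794, the smallest this design allows). Adjusted by Benjamini-Hochberg over the 7 library measures tested, the permutation p was 0.0556, which is the lowest this adjustment can give when 1 measure alone separates the groups, so it could not have passed 0.05 and does not bear on the separation. The closest ewes of opposite groups were P4 replicate 3, at 2.42, and P4+RU486 replicate 5, at -0.91. Within each group the shallowest libraries also had the lowest scores. In P4+RU486 these were replicates 1 and 2, with relative depths of 0.882 and 0.877 and scores of -41.1 and -41.2. In P4, replicate 3 was lowest in both. Relative depth did not differ detectably between the groups (exact permutation test, two-sided, p = 0.659). Whether depth adds to this component was not tested. The second component, with 20.5% of the variance, set P4+RU486 replicate 2 apart at -44.6, against 18.4 to 22.7 in the other 4 ewes of its group. Across genes, the median correlation between ewes was 0.971 within P4, 0.956 within P4+RU486 and 0.951 between the groups. The mean correlation within P4+RU486 minus that within P4 was -0.0149, a difference that was not shown beyond chance (exact permutation test, two-sided, p = 0.238). Without P4+RU486 replicate 2 the difference over the same genes was -0.0056 (exact permutation test, two-sided, p = 0.786).

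**Figure D1:**
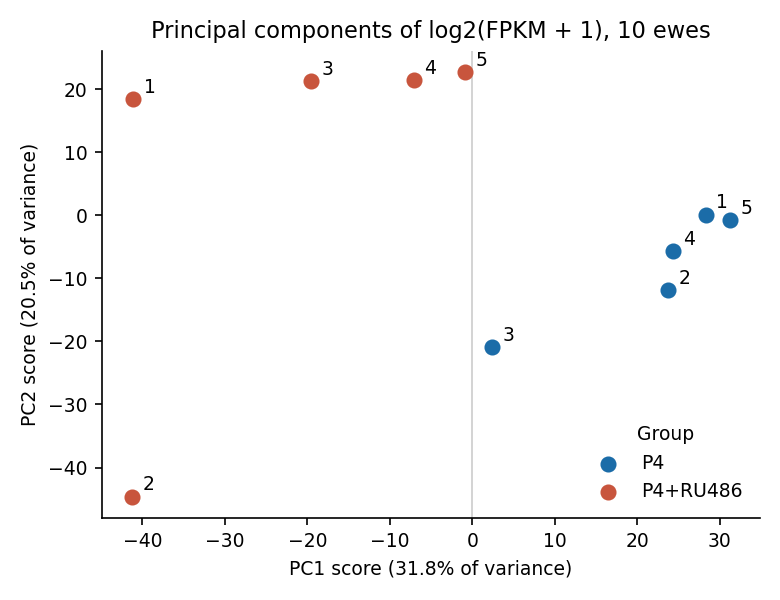
Scores of the 10 ewes on the first and second principal components of log2(FPKM + 1) over 14866 genes, with each point an ewe labelled by its replicate number and coloured by group. All P4 ewes lie right of all P4+RU486 ewes on the first component, and P4+RU486 replicate 2 lies alone at -44.6 on the second.

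Among genes called by limma, more were lower than higher under RU486, and the lower ones had the larger median change. This did not extend to genes counted only for having no overlap between the groups, of which 553 were higher and 516 lower in P4+RU486. Of 23019 genes tested, 557 differed between the groups, 319 of them lower and 238 higher in P4+RU486 than in P4 (limma, FDR under 0.05, 5 ewes against 5). The lower genes fell by a median of 0.92 on the log2 scale, and the median rise of the higher genes was 0.65. Among the 194 genes that changed at least 2-fold, 142 were lower and 52 higher, so 73.2% of these large changes were losses. Across all alternatives run, the share of losses among the 2-fold changes lay between 70.4% and 85.7%. The share among all calls was 57.3%, and between 51.2% (quantile normalisation) and 88.2% (Bonferroni). The median log2 fold change of all genes was 0. In total 4073 genes had an unadjusted p under 0.05.

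The number of called genes depended on single ewes. Leaving out P4+RU486 replicate 2 raised the count to 1024. Leaving out P4+RU486 replicate 1, 3 or 4 lowered it to 250, 202 and 360, and leaving out P4 replicate 1, 2, 4 or 5 lowered it to 222, 234, 181 and 183. The count was 559 without P4+RU486 replicate 5 and 523 without P4 replicate 3. All 557 genes called with all ewes kept the sign of their fold change in every set of 9. For the 530 of them with no overlap between the groups this was fixed in advance, so it adds no support. With all ewes and in every set of 9, 143 genes were called, of which 100 were lower and 43 higher in P4+RU486.

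**Figure D2:**
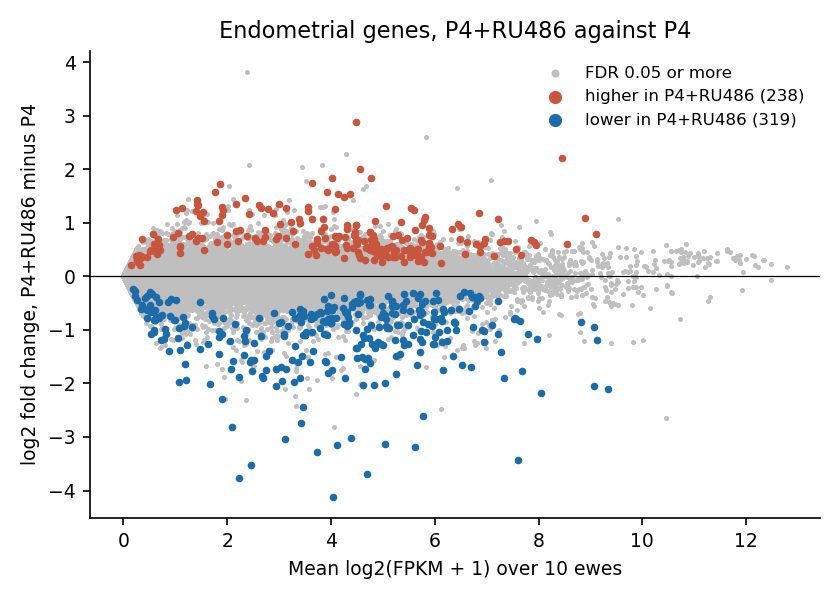
Log2 fold change (P4+RU486 minus P4) of 23019 genes against their mean log2(FPKM + 1) over 10 ewes, with genes called at an FDR under 0.05 in colour. The 319 lower genes reach -4.11 and the 238 higher genes reach 2.88.

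Called genes were found in every band of expression. The share called rose from 0.748% of the 8153 genes with a mean log2(FPKM + 1) under 1 to 2.31% between 1 and 3, 3.21% between 3 and 5, 4.6% between 5 and 7 and 4.19% at 7 or more. In each of these bands more genes were lower than higher in P4+RU486, for example 114 lower and 88 higher between 3 and 5. Among the 100 genes of highest mean expression, 0 were called by limma in either direction, 6 had an unadjusted limma p under 0.05 and 5 were called in the authors' deposited table. The called lower genes together made up 2.84% ± 0.156 of the summed FPKM in P4 and 1.21% ± 0.146 in P4+RU486 (SD, n = 5 each). The called higher genes made up 0.973% ± 0.0187 in P4 and 1.62% ± 0.248 in P4+RU486 (SD, n = 5 each). These shares describe genes selected for the difference and are not a separate test of it.

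Genes whose values did not overlap between the groups were counted without a model. Among the 14866 expressed genes, 1069 had all 5 ewes of one group beyond all 5 of the other, 553 of them higher and 516 lower in P4+RU486. This was 7.19% of the genes, where chance gives 0.794%, or 118 genes, on average. The number varied widely between splits of the ewes into 5 and 5. In 100 splits drawn of 126 possible, the real one included, the others gave a median of 59 and at most 891. The split with 891 exchanged only 1 ewe of each group, P4 replicate 3 and P4+RU486 replicate 5. It therefore kept most of the treatment contrast and does not show the spread by chance alone. Of the 557 called genes, 530 showed no overlap between the groups. The count for 9 ewes, where chance gives 236 genes on average, was 1948 without P4+RU486 replicate 2, 1924 without P4 replicate 3 and 1645 without P4+RU486 replicate 5.

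Among called genes with no overlap between the groups and a mean log2(FPKM + 1) of at least 1, the lowest fold change on the log2(FPKM + 1) scale was that of ENSOARG00000012631, at 78.6 ± 47.4 FPKM in P4 and 3.73 ± 3.48 FPKM in P4+RU486 (SD, n = 5 each), a ratio of means of 21.1. Some called genes of lower expression had larger ratios of means, which the added 1 FPKM reduces on this scale. Its log2 fold change was -4.11 (SE 0.51, 95% interval -5.25 to -2.98, limma adjusted p = 0.00592). ENSOARG00000014723 was at 120 ± 76.9 FPKM in P4 and 6.43 ± 1.83 FPKM in P4+RU486 (SD, n = 5 each), with a log2 fold change of -3.69 (SE 0.55, limma adjusted p = 0.0132). Its P4 values ran from 19.5 to 203 FPKM and its P4+RU486 values from 4.39 to 8.45 FPKM. In the other direction, ENSOARG00000012862 was an abundant transcript that rose from 167 ± 42.8 FPKM in P4 to 782 ± 239 FPKM in P4+RU486 (SD, n = 5 each), a log2 fold change of 2.20 (SE 0.23, limma adjusted p = 0.00265). ENSOARG00000010002 rose from 8.57 ± 5.97 to 78.9 ± 60.1 FPKM (SD, n = 5 each), a log2 fold change of 2.88 (SE 0.62, limma adjusted p = 0.0442). The groups barely parted for this gene, with a highest P4 ewe of 17.2 FPKM and a lowest P4+RU486 ewe of 17.6 FPKM. Its call was lost when any ewe except P4+RU486 replicate 2 was left out, with limma adjusted p between 0.0594 and 0.107, and with a pseudocount of 5 (limma adjusted p = 0.0554), whereas the other 3 genes stayed under 0.05 in these settings. For each of the 4 genes the exact permutation test, two-sided, gave p = 0.00794, the smallest possible here. The genes were picked for having no overlap between the groups, which fixes this p in advance, so it adds no support. Which proteins these identifiers encode is not given in the sources used here.

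**Figure D3:**
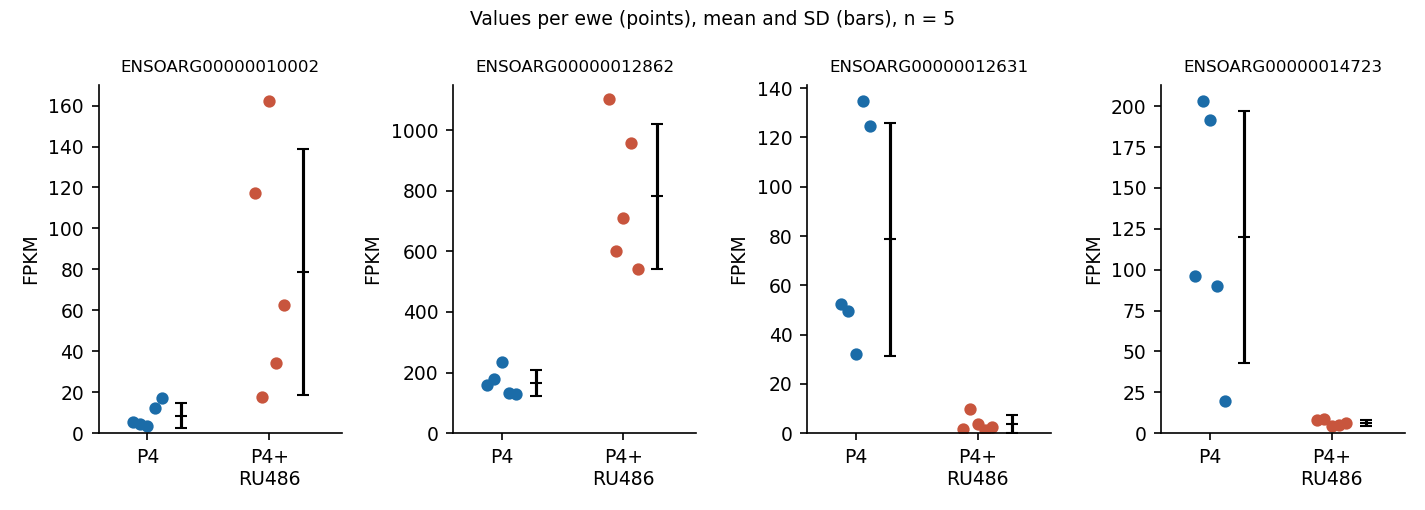
FPKM per ewe (points) in P4 and P4+RU486 for the 2 genes with the highest and the 2 with the lowest fold change on the log2(FPKM + 1) scale among called genes without overlap and with a mean of at least 1, with the mean and SD beside each group (n = 5, linear axes from 0). ENSOARG00000012862 runs from 131 to 235 FPKM in P4 and from 543 to 1102 FPKM in P4+RU486, and ENSOARG00000012631 from 32.0 to 135 FPKM in P4 and from 1.19 to 9.66 FPKM in P4+RU486.

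Ewes were also placed between the groups on genes chosen without them. With an ewe held out, genes were called on the other 9 ewes, and the ewe was placed on a line from their P4 mean (position 0) to their P4+RU486 mean (position 1). Held-out P4 ewes lay at 0.11 ± 0.0493 and held-out P4+RU486 ewes at 0.868 ± 0.166 (SD, n = 5 each). The lowest P4+RU486 position was 0.651, in replicate 2, and the highest P4 position was 0.167, in replicate 1. Counted gene by gene, 50.1% of the 1024 genes used for P4+RU486 replicate 2 and 65.1% of those used for replicate 5 lay on the P4+RU486 side of the midpoint, so by this measure replicate 2 was no nearer to its group than to P4. The genes used numbered between 181 and 1024.

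The authors' deposited table called 1611 genes at an adjusted p under 0.05, which is more than the 557 of limma on the FPKM values. By the mean FPKM of the groups, 931 of the genes called in the authors' deposited table were lower in P4+RU486 and 680 higher, so 57.8% were losses. Of the 557 limma calls, 507 (91.0%) were also called in the authors' deposited table, and 50 were not. The table gives no fold change by the authors, so directions were not compared. Of the 1611 genes, 292 in the authors' deposited table had a mean log2(FPKM + 1) under 1, against 61 of the limma calls. In the authors' deposited table the adjusted p of the 4 named genes was 1.5e-17 for ENSOARG00000012631, 5.13e-22 for ENSOARG00000014723, 2.43e-19 for ENSOARG00000012862 and 1.04e-07 for ENSOARG00000010002.

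One library differed from the rest in how its values were spread over abundant and rare transcripts. In P4+RU486 replicate 2, the 355 genes with a mean log2(FPKM + 1) of 8 or more lay above the median of the other ewes by a median of 0.61, and the 5174 genes between 2 and 4 had a median difference of -0.14. The difference of these medians was 0.75 in this ewe, and between -0.23 and 0.25 in the other 9. The 100 most abundant genes took 37.3% of its summed FPKM, against 25.1% to 31.9% in the others. Over all ewes, neither that share (28.7% ± 2.57 in P4, 31.8% ± 3.26 in P4+RU486, SD, n = 5 each; exact permutation test, two-sided, p = 0.111) nor the difference of medians (exact permutation test, two-sided, p = 0.643) was shown to differ between the groups.

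**Figure D4:**
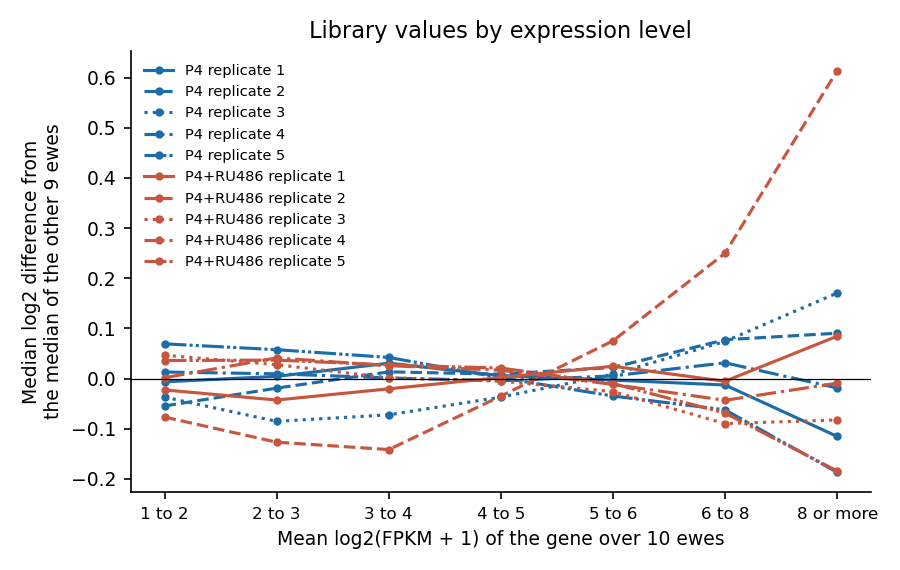
Median log2 difference of each ewe from the median of the other 9, by band of mean log2(FPKM + 1), with 1 line per ewe coloured by group. P4+RU486 replicate 2 climbs from -0.14 in the band from 3 to 4 to 0.61 in the band from 8, while the other ewes stay within 0.2 of 0 in the band from 8.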

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

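The tests of P4+RU486 replicate 2 in this part were chosen after its values were seen, and the counts over splits of the ewes before. Each of 24 groups of 5 values was searched with Dixon's ratio for an ewe far from the rest. In 4 of them one was found, where chance gives about 1.2 for normally distributed values. The measures are related, and the 4 came from P4+RU486 replicate 2 and P4 replicate 3 alone, so 4 against 1.2 is not a test. P4+RU486 replicate 2 had a summed expression of 965174 FPKM, against 704242 to 765735 in its group, and a second-component score of -44.6, against 18.4 to 22.7. P4 replicate 3 had a relative depth of 0.773, against 1.05 to 1.13 in its group, and a first-component score of 2.42, against 23.8 to 31.2.

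In P4+RU486 replicate 2, abundant genes were high and rarer genes low relative to the other ewes, with a difference of medians of 0.75 on the log2 scale. By the estimated relative depth, lower sequencing depth is argued against as the whole cause. The library estimated as shallowest, P4 replicate 3, had a difference of only 0.248, and the SD over the other 9 ewes was 0.16. Genes at 0 rank these libraries the other way, with 3904 in P4+RU486 replicate 2 and 3745 in P4 replicate 3. The argument therefore rests on the estimate alone, which would include any further scaling of the libraries, and lower depth is not excluded. Whether a few genes took most of the values could not be decided. Without the 100 most abundant genes this library still summed to 604926 FPKM, against 501034 to 549008 in the others. The scaling of the libraries is not given, however, and it could raise that sum by itself. As a share, those 100 genes took 37.3% of its summed FPKM, against 25.1% to 31.9% in the others. RU486 treatment alone is argued against, since the highest of the other 4 treated ewes was 0.114. RNA quality was not tested, as no integrity values or reads were used here. The makeup of the dissected tissue was not tested, because it needs gene names. Both stay open.

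Chance is argued against for the contrast between the groups as a whole. It is not excluded, since 1 of 100 splits is the lowest share this test can give. Of 100 splits of the ewes into 5 and 5 (of 126 possible, the real one included), 1, the real split, gave 557 genes, and the highest other gave 4. The same held for the genes differing at least 2-fold (194, highest other 1), the genes of the larger direction (319, highest other 2) and those of the smaller (238, highest other 2), each reached by 1 split. For the genes without overlap between the groups the real split, 1 of 100, gave 1069, but the highest other gave 891. That split exchanged P4 replicate 3 with P4+RU486 replicate 5, the closest ewes of opposite groups on the first component. All of these counts come from the same splits and are not separate tests.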

How the results depend on the processing

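The counts and the named genes kept their direction in each alternative they were computed for, up to 24, and the median shift of all genes lay around 0, between -0.00287 and 0.00874. For the named genes, leaving out an ewe or changing the pseudocount could not reverse the direction, since they were picked for having no overlap between the groups. The separation on the first principal component kept its direction and an unadjusted exact permutation p between 0.00794 and 0.0238 in the alternatives it was computed for. The count of called genes stayed within 1.5 times of 557 under both filters on mean expression, both pseudocounts, median-ratio rescaling and quantile normalisation. Centring on the median gene moved nothing, since that median was 0, and so tests nothing. Other thresholds gave 70 calls (17 higher, 53 lower) at an FDR under 0.01, 1188 (556 higher, 632 lower) at an FDR under 0.10, 194 (52 higher, 142 lower) with a minimum log2 change of 1, and 17 (2 higher, 15 lower) with Bonferroni adjustment. Array weights, which give outlying libraries less say, gave 1312 calls (624 higher, 688 lower). The authors' adjusted p gave 1611 (680 higher, 931 lower), and a filter at a mean log2 of 1 without P4+RU486 replicate 2 gave 1394 (617 higher, 777 lower). For genes at least 2-fold higher and lower, the counts were 12 and 42 at an FDR under 0.01, 2 and 12 with Bonferroni, 15 and 83 with a pseudocount of 5, and 89 and 261 with the authors' adjusted p. The 2-fold higher genes alone moved to 79 with a pseudocount of 0.1 and to 83 with the filter and without P4+RU486 replicate 2. Leaving out 1 ewe at a time gave between 181 and 1024 calls, 54 to 429 higher and 124 to 595 lower, with 20 to 70 genes at least 2-fold higher and 82 to 169 at least 2-fold lower. The fewest calls came without P4 replicate 4 and the most without P4+RU486 replicate 2. Genes without overlap between the groups numbered 1177 to 1948 in the sets of 9 ewes, where chance gives 236 of 14866 genes on average. They numbered 1948 with the filter and without P4+RU486 replicate 2. The cause of these moves was not tested beyond the smaller number of ewes or the changed threshold. No paired analysis was possible because the replicate numbers only name the ewes. Other size factors, another count model, a filter on low counts, gene lists and centring on ribosomal protein genes were not run, since the table holds no counts and no gene names. The depth is unknown, so what depth limits at low expression could not be worked out.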

Other observations

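The tests of treatment and depth in this part were chosen after the values were seen, and the permutation of the splits before. Some genes in this endometrium had a wide gap in expression between ewes. The search asked for a gap of at least 3 log2 units between neighbouring ewes (on log2(FPKM + 0.1)), at least 2 ewes on each side and a highest value of at least 5 FPKM, and it found 19 genes. It set no limit on the spread on either side of the gap, which in some of these genes was wider than the gap. In 0 of the 19 did the gap part the treatment groups completely. In 5 of them the high ewes were all of one group, and in 3 the low ewes were, which was not tested against chance. Limma called 1 of the 19, which was high in 4 P4 and 0 P4+RU486 ewes (limma adjusted p = 0.0478). The widest gap was in ENSOARG00000008077, chosen after its values were seen, as was its partner below. It stood at 286 to 440 FPKM in 6 ewes (4 P4+RU486 and 2 P4) and at 2.51 to 5.07 FPKM in the other 4. The same ewes were high and low for ENSOARG00000009526, at 63.3 to 103 FPKM and 0.54 to 3.30 FPKM.

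RU486 treatment is argued against as the cause for this pair, since 3 ewes would be on the wrong side of the gap. Library depth differed too little to make such a gap: the deepest library exceeded the shallowest by a factor of 1.5, while the smaller gap of the pair was 18.7-fold. This held in advance for any gene found, since the search asked for a gap of at least 3 log2 units. A candidate explanation is an inherited difference between ewes, such as a deleted or poorly aligned allele that covers both genes, which was not tested, as it needs reads and positions. Reads shared between similar genes stay open for the same reason. Over all 19 genes, 3 pairs had the same ewes on each side, where permuting the ewes of each gene gave 1.3 on average (10000 permutations, p = 0.125), so sharing of splits beyond genes varying independently of each other was not shown with so few genes.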
